A study of Mus musculus with 2 samples.

How the data were processed

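The samples were 2 poly(A)-selected RNA-seq libraries of the mouse erythroid line G1E-ER4 after 24 hours in 10 nM 17beta-estradiol, which the labels call biological replicates 1 and 2. They form 1 group, and no untreated or other control library was analysed here. No condition was therefore compared with another, and no p-value is given for a gene or a gene list. An exact sign-flip test over 2 libraries cannot give a p below 0.5, so the ratios carry a mean and an SD alone.

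Per the deposited file manifests, the reads were aligned and quantified on the mm10 assembly with the GENCODE M4 annotation, 1 library per file. The names and versions of the aligner and of the quantifier are not given in the sources used here. Per the file headers, each table holds an expected count for every gene or transcript, which is an estimate that shares a read among the places it fits and need not be whole. The same tables hold TPM as deposited by the authors, in which the expected count is divided by effective length and scaled so that each library sums to 1000000. A second TPM column, the posterior mean, contains a prior count, so rows without a read hold values above 0 in it. Per the file headers, the transcript tables also give the percent of a gene's TPM that each transcript holds. The deposited bounds on TPM refer to the posterior estimate and their level is not stated in the files, so they were not used as errors. A counting interval had been planned for each ratio, and the SD over both libraries is given in its place. The difference between length and effective length corresponds to reads of 36 bases. The sources used here do not state whether counting used strand.

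The gene table had 69691 rows, of which 43346 carried an Ensembl gene identifier, 26248 only a number and 97 a spike-in or phiX name. Gene symbols, classes and coordinates came from GENCODE M21, which uses the same assembly, and 42462 identifiers matched it. Matched genes held 99.8% of the expected counts in each library. The numbered rows name no gene and were kept out of detection, correlation, dispersion and fold counts. This choice was made after the values had been seen, and it matters for the correlation, so the values with those rows are printed beside the others. Numbered rows held 2427 expected counts in replicate 1 and 2041 in replicate 2, and the spike-in rows 0.

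Depth was 20412826 expected counts in replicate 1 and 18564086 in replicate 2. A gene without a read could have held up to 3 counts, or 0.147 and 0.162 CPM in the respective library. Intervals and floors cover counting error only, since reads were counted without molecular identifiers.

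A gene was called detected at 1 TPM or more in both libraries. Replicates were compared by Pearson and Spearman correlation of log2(TPM + 1) across genes at 1 TPM or more in either library, with the SD taken from 200 resamplings of the genes. Genes are not independent replicates, so no p-value was attached. The biological coefficient of variation was the square root of the common dispersion from edgeR 4.0.16 in R 4.3.3, fitted with an intercept alone to expected counts rounded to whole numbers, with TMM scaling, over genes with at least 10 counts in both libraries. Genes that differed over 2-fold were counted among those with at least 50 rounded counts on average after TMM scaling, beside 100 library pairs simulated with Poisson noise alone. For named genes the ratio has an exact 95% Clopper-Pearson interval. Where 1 library had 0 counts, the ratio was bounded against 3 counts, and genes tied in this way were ordered by that bound, which is not printed.

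A total of 26 gene lists, 15 ratios and 40 genes for isoforms were fixed before the data were examined. The median of a list's mean TPM was placed among 10000 random lists of as many nuclear protein-coding genes, matched on transcript length in 10 bins, and its percentile describes these libraries only. Random lists of equal median counted evenly as lower and higher. A list with a median of 0 TPM therefore has a percentile set only by how many random lists also had 0. In 1 alternative, random lists were drawn from genes at 1 TPM or more in both libraries, while each list kept its undetected members. That setting lowers the percentile of a list with undetected members by construction. Isoform shares were taken for genes with at least 20 expected counts in both libraries. The rule for named genes, also fixed before the data were examined, took 4 sets. These were the 10 most abundant nuclear protein-coding genes, up to 4 members per list together with a fixed set of globin, regulator and label-check genes, the 5 genes most different in each direction, and up to 8 isoform genes with shared transcripts plus up to 4 whose leading transcript differed. List members named because they had few or 0 counts, genes named as having 1 transcript, and genes named outside this rule in the closing section were chosen after their values were seen. Values of some genes that the rule takes are not reported here. Some list members had no matching row here and are not analysed, namely Hbb-b1, Hbb-b2, Rhce, Ahsp and Hist1h2bm.

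To find genes whose reads cannot be assigned with certainty, every 36-base window of a gene's longest M21 transcript was searched in the transcripts of all other genes on both strands. Windows found only in a gene's other transcripts were not scored. The share of windows found in no other gene is called the unique share. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for these steps.

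The steps were tested on simulated data. For a library pair drawn with a coefficient of variation of 10% and no changed gene, 10.0% was recovered over 11175 genes. With 200 genes changed by 1.5-, 3-, 4- or 8-fold, the same estimate came to 17.0% over 11178 genes, so it also takes up large differences in a few genes. In that pair the 2-fold rule found 6% of the 50 genes changed 1.5-fold and 100% of the 50 genes at each of the larger folds, and it also called 1 of 9177 unchanged genes. Of 200 random lists, 1.5% lay above the central 95% of random lists.

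Alternatives covered other TPM and count thresholds, posterior mean TPM, pseudocounts, DESeq2 1.42.0 size factors, total-count scaling, other random lists, other denominators and each library alone. Alternatives restricted to genes with unique shares of at least 90%, restricted to nuclear protein-coding genes in the correlation, or including the numbered rows were added after seeing the data.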

Results

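The series measured polyadenylated RNA by single-end sequencing in G1E-ER4 cells, a mouse erythroid line derived from Gata1-null cells in which a GATA-1 protein fused to an oestrogen receptor domain is activated by hormone. The cells had been exposed to 10 nM 17beta-estradiol for 24 hours. Both libraries belong to 1 group, biological replicates 1 and 2, with 20412826 and 18564086 expected counts. The values below describe the induced state alone, and values with ± are the mean and SD over n = 2.

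The induced cells carried large amounts of adult globin mRNA. Hbb-bs, an adult beta-globin gene, was the most abundant nuclear protein-coding gene at 65450 ± 6047 TPM (SD, n = 2), and Hba-a2, an adult alpha-globin gene, followed at 39024 ± 4526 TPM. Hba-a1 stood at 8836 ± 1175 TPM and Hbb-bt at 602 ± 142 TPM. The 4 adult globins together held 11.4% ± 1.19 (SD, n = 2) of all TPM, with 10.6% in replicate 1 and 12.2% in replicate 2. The adult globin list had a median of 23930 TPM, at the percentile of 100 among random lists. Hbb-bs lies on chromosome 7 from 103826534 to 103828096 and Hba-a2 on chromosome 11 from 32296489 to 32297298 (GRCm38).

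Of the 7 embryonic and minor globins, 4 were detected in both libraries. Hbb-bh1, an embryonic beta-like globin, reached 45.8 ± 6.77 TPM, Hbq1b 27.045 ± 6.36 TPM, the embryonic alpha-like Hba-x 22.7 ± 2.33 TPM and Hbb-y 1.37 ± 0.382 TPM. The list median was 1.37 TPM, at the percentile of 96.8, but of 70.4 among random lists not matched on length. Among genes at 1 TPM or more its percentile was 0, with undetected members kept in the list. The sum of Hbb-bh1 and Hbb-y was 1405-fold below the sum of Hbb-bs and Hbb-bt, a log2 ratio of -10.46 ± 0.08 (SD, n = 2). Adult alpha globins summed to less than adult beta globins, with a log2 ratio of -0.47 ± 0.04 and the same sign in both libraries. Hbb-bs exceeded Hbb-bt by 6.78 ± 0.21 on the log2 scale, and Hba-a1 lay below Hba-a2 at -2.14 ± 0.02. The adult copies are near-identical, with unique shares of 33.4% for Hbb-bs, 40.9% for Hbb-bt, 29.7% for Hba-a1 and 10.0% for Hba-a2, so the division between copies is uncertain.

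Besides Hbb-bs, Hba-a2 and Hba-a1, the 10 most abundant nuclear protein-coding genes included the ferritin light chain gene Ftl1 at 10766 ± 451 TPM, the ribosomal protein genes Rpl28 at 7344 ± 525 TPM, Rpl41 at 6813 ± 578 TPM and Rps26 at 6499 ± 21.8 TPM, the elongation factor gene Eef1a1 at 7096 ± 277 TPM and Ptma at 6774 ± 152 TPM. Gm11808, a gene model with a unique share of 5.33%, was listed at 5226 ± 182 TPM. Ribosomal protein genes held 11.9% ± 0.257 of TPM and mitochondrially encoded genes 5.29% ± 0.311. The 10 most abundant genes of a library held 18.0% ± 1.08 of TPM and the 100 most abundant 42.1% ± 0.663. TPM gives short mRNAs more weight than expected counts do, and as shares of expected counts the adult globins held 4.79%, ribosomal protein genes 5.96%, mitochondrially encoded genes 2.80%, the 10 most abundant genes 9.88% and the 100 most abundant 27.7%. Eef1a1, with a unique share of 28.2%, shares much of its sequence with other genes. In all, 10390 genes, or 10813 rows with the numbered rows included, were detected in both libraries. Of the genes, 8853 were annotated as protein-coding and 743 as processed pseudogenes. Processed pseudogenes held 7.64% of TPM. Reads assigned to them may also fit other genes, so the 743 are not shown to be transcribed.

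Genes of haem synthesis were detected throughout. All 9 enzymes of the list passed 1 TPM in both libraries and 7 passed 100 TPM, among them Alad at 1401 ± 129 TPM, the erythroid first-step enzyme gene Alas2 at 918 ± 16.2 TPM and Cpox at 572 ± 40.1 TPM. Alas1, the housekeeping form of the first enzyme, stood at 6.15 ± 0.771 TPM, and Alas2 exceeded it by 7.23 ± 0.16 on the log2 scale (SD, n = 2). All 20 genes of iron uptake and handling were detected, with Fth1 at 2798 ± 183 TPM, the mitochondrial transporter gene Abcb10 at 500 ± 28.7 TPM and Slc25a39 at 457 ± 61.3 TPM. Fth1 lay below Ftl1 at a log2 ratio of -1.94 ± 0.03, with the reservation that Ftl1 had a unique share of 6.22%. The transferrin receptor gene Tfrc exceeded Tfr2 by 4.06 ± 0.27 on the log2 scale. The medians of these 2 lists, 423 and 153 TPM, both lay at the percentile of 100 among random lists.

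Of the 26 measured genes of the red cell membrane and its skeleton, 25 were detected and 16 passed 100 TPM. The spectrin gene Sptb reached 853 ± 44.9 TPM, Slc4a1, which encodes the band 3 anion exchanger, 600 ± 31.4 TPM, the adducin gene Add2 595 ± 31.6 TPM and the ankyrin gene Ank1 404 ± 23.0 TPM. Aqp1, with 0.02 TPM in replicate 1 and 0 in replicate 2, was the member that was not detected. All 24 measured genes of glycolysis and redox defence were detected, led by Aldoa at 4592 ± 245 TPM, Gapdh at 4379 ± 312 TPM, the carbonic anhydrase gene Car2 at 2508 ± 91.1 TPM and Ldha at 2374 ± 0.566 TPM. Car2 exceeded Car1 by 4.71 ± 0.07 on the log2 scale, and Pkm exceeded Pklr, the red cell form of pyruvate kinase, by 2.16 ± 0.01. The list medians were 168 TPM for the membrane and 553 TPM for glycolysis and redox, each at the percentile of 100.

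All 22 erythroid transcription factor genes were detected, and 10 passed 100 TPM. Gata1, on chromosome X from 7959260 to 7978071, was the highest at 2947 ± 330 TPM, with 80861 and 86527 expected counts. Its cofactor gene Zfpm1 followed at 897 ± 67.7 TPM, then Gfi1b at 503 ± 51.0 TPM and Klf1, which encodes an activator of the beta-globin gene, at 412 ± 1.62 TPM. The values do not tell apart reads from a chromosomal Gata1 gene and from the introduced construct. The list median was 97.03 TPM, at the percentile of 100.

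Genes of the progenitor stage were lower. Gata2, which encodes an earlier-acting GATA factor, stood at 6.32 ± 0.156 TPM, the stem cell factor receptor gene Kit at 12.3 ± 0.530 TPM and the myeloid regulator gene Spi1 at 18.8 ± 0.509 TPM. Gata1 exceeded Gata2 by 8.86 ± 0.13 and Klf1 exceeded Spi1 by 4.46 ± 0.04 on the log2 scale (SD, n = 2). The ratio of Gata1 to Gata2 may include reads of the introduced construct, so it does not measure the chromosomal genes alone. Myc stood at 91.8 ± 7.87 TPM, Runx1 at 53.0 ± 1.34 TPM and Hhex at 29.045 ± 4.87 TPM, and the cytokine receptor gene Csf2rb was the highest member at 544 ± 42.2 TPM. Of the 20 members 14 were detected, and Cd34 and Hoxa9 had 0 counts in both libraries. The list median of 6.19 TPM lay at the percentile of 89.5. Among genes at 1 TPM or more its percentile was 0.11, with undetected members kept in the list. Without uninduced cells, none of these levels can be read as a change.

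**Figure D1:**
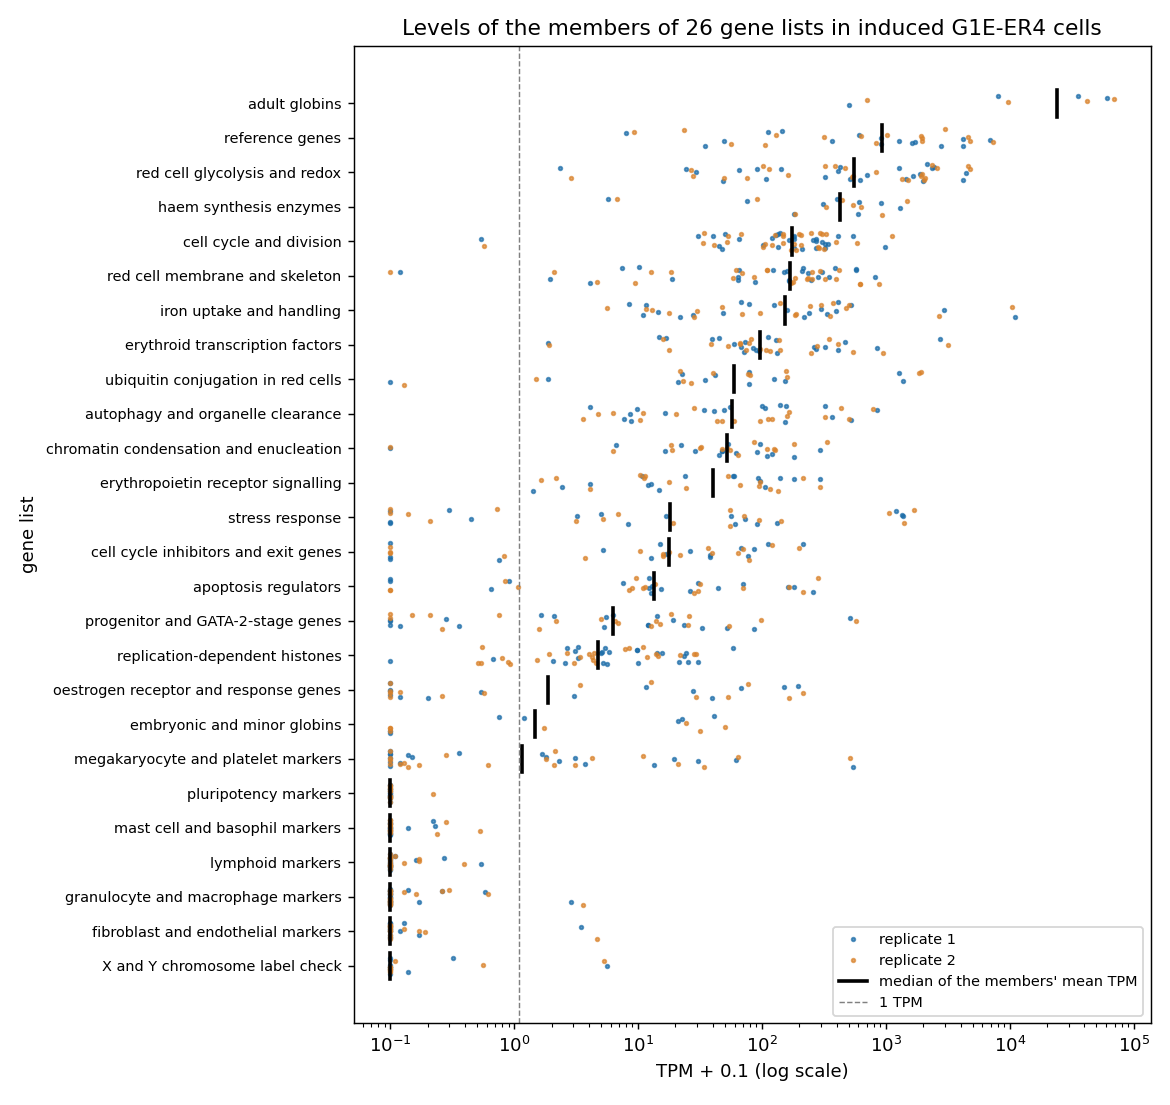
Each point is 1 gene of the list named on the vertical axis in 1 replicate, placed by TPM + 0.1 on a log scale, and the black bar is the median of the members' mean TPM. Adult globins lie highest, with a median of 23930 TPM, and 6 lists have a median of 0 TPM.

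All 16 genes of erythropoietin receptor signalling were detected, with a list median of 39.98 TPM, at the percentile of 99.97, but of 95.8 among random lists of genes at 1 TPM or more. The kinase gene Pim1 reached 295 ± 1.89 TPM, the anti-apoptotic gene Bcl2l1 197 ± 23.7 TPM, the feedback inhibitor gene Cish 137 ± 4.72 TPM and Podxl 111 ± 7.57 TPM. Among 17 apoptosis regulators 13 were detected, including Trp53 at 271 ± 19.1 TPM, Bax at 164 ± 1.29 TPM and Bak1 at 70.3 ± 0.346 TPM. Bcl2l1 exceeded its relatives Bcl2 by 7.98 ± 0.25 and Mcl1 by 2.40 ± 0.50 on the log2 scale. Of the Bcl2l1 TPM, 36.8% in replicate 1 and 43.5% in replicate 2 lay on Bcl2l1-209, of 961 bases without annotated coding sequence. These ratios are therefore not of coding mRNA alone. The apoptosis list had a median of 13.3 TPM, at the percentile of 98.6 among all nuclear protein-coding genes. Among genes at 1 TPM or more its percentile was 14.9, which is lowered by construction, since the undetected members stayed in the list.

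All 19 genes of autophagy and organelle clearance were detected, among them Bnip3l, which acts in the removal of mitochondria from red cells, at 824 ± 43.9 TPM, Gabarap at 515 ± 16.8 TPM, Sqstm1 at 400 ± 43.2 TPM and Bnip3 at 320 ± 1.10 TPM. Of the 12 ubiquitin genes 11 were detected, among them the polyubiquitin gene Ubb at 1611 ± 337 TPM, Rnf10 at 156 ± 6.10 TPM and Ube2l6 at 141 ± 23.1 TPM. For chromatin condensation and enucleation 15 of 16 genes were detected, with Rac2 at 315 ± 30.9 TPM, Dnase2a at 180 ± 0.389 TPM, Tmcc2 at 123 ± 4.81 TPM and Kmt5a at 111 ± 20.02 TPM. The medians of these 3 lists were 56.9, 59.2 and 52.0 TPM, at percentiles of 100, 99.99 and 100. Levels of Bnip3 and Ubb are uncertain, since their unique shares were 28.5% and 34.8%. The coding transcript Bnip3l-201 held only 6.18% of Bnip3l TPM in replicate 1 and 5.28% in replicate 2. Nearly all the rest lay on transcripts of 354, 446 and 789 bases without annotated coding sequence. Their TPM depends on their short length, so the Bnip3l level is not that of coding mRNA alone.

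Genes of cell division were abundant in the induced cells. Of 30 members 29 were detected and 23 passed 100 TPM, led by the cyclin gene Ccnd3 at 1048 ± 103 TPM, Cdk4 at 563 ± 30.9 TPM and the replication genes Mcm3 at 401 ± 10.4 TPM and Mcm7 at 328 ± 4.27 TPM. The list median of 175 TPM lay at the percentile of 100. Ccnd3 exceeded Ccnd2 by 5.04 ± 0.04 on the log2 scale, and Ccnd1 was not detected, at 0.44 and 0.47 TPM. Of 17 cell cycle inhibitors and exit genes 13 were detected, with Btg2 at 206 ± 11.2 TPM, Cdkn1a at 117 ± 5.98 TPM, Gadd45a at 82.5 ± 6.13 TPM and Cdkn1b at 74.1 ± 4.99 TPM. Cdkn1b lay below Cdkn1a at a log2 ratio of -0.66 ± 0.17. The inhibitor list had a median of 17.6 TPM, at the percentile of 99.4 among all nuclear protein-coding genes. Among those at 1 TPM or more its percentile was 27.7, with undetected members kept in the list.

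Markers of other blood lineages were mostly near 0. None of 16 mast cell and basophil genes was detected, and Cpa3 had 1 and 0 counts. Of 23 granulocyte and macrophage genes only Cd68 was detected, at 3.14 ± 0.530 TPM, and of 19 lymphoid genes none, with Cd79a the highest at 0.365 ± 0.106 TPM. Of 16 fibroblast and endothelial genes only Fn1 was detected, at 3.98 ± 0.884 TPM, and of 13 pluripotency genes none. The medians of these 5 lists were 0 TPM, at percentiles of 16.3, 21.9, 9.96, 2.23 and 16.8 in the same order. At a median of 0 these percentiles are set by ties alone and do not rank the lists. With posterior mean TPM they were 2.96, 3.6, 1.2, 0.955 and 18.06. All rose with either library left out, that of the fibroblast and endothelial list to 4.54 without replicate 1 and 4.405 without replicate 2. Megakaryocyte and platelet genes differed from these lists, with 10 of 20 detected, namely Nrgn at 526 ± 19.7 TPM, Tubb1 at 62.8 ± 2.09 TPM, Gp1ba at 32.1 ± 2.71 TPM and Pf4 at 20.04 ± 0.990 TPM among them. The megakaryocyte list had a median of 1.05 TPM, at the percentile of 78.6. Among genes at 1 TPM or more its percentile was 0, with undetected members kept in the list.

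Among 14 oestrogen receptor and response genes 7 were detected, with the protease gene Ctsd at 205 ± 11.1 TPM, Ncoa2 at 72.7 ± 6.58 TPM and Ncoa3 at 46.5 ± 9.91 TPM. Esr1, the oestrogen receptor alpha gene on chromosome 10 from 4611593 to 5005614, stood at 158 ± 10.8 TPM. Of its reads, 97.7% in replicate 1 and 97.2% in replicate 2 were assigned to Esr1-208, a transcript of 1019 bases without annotated coding sequence. Its exons 2 to 5 overlap exons 6 to 9 of the full-length Esr1-201, and no read was assigned to Esr1-201. The receptor target genes Pgr, Greb1 and Tff1 had 0 counts in both libraries, and the list median was 1.78 TPM, at the percentile of 68.2. Among genes at 1 TPM or more its percentile was 0, with undetected members kept in the list.

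**Figure D2:**
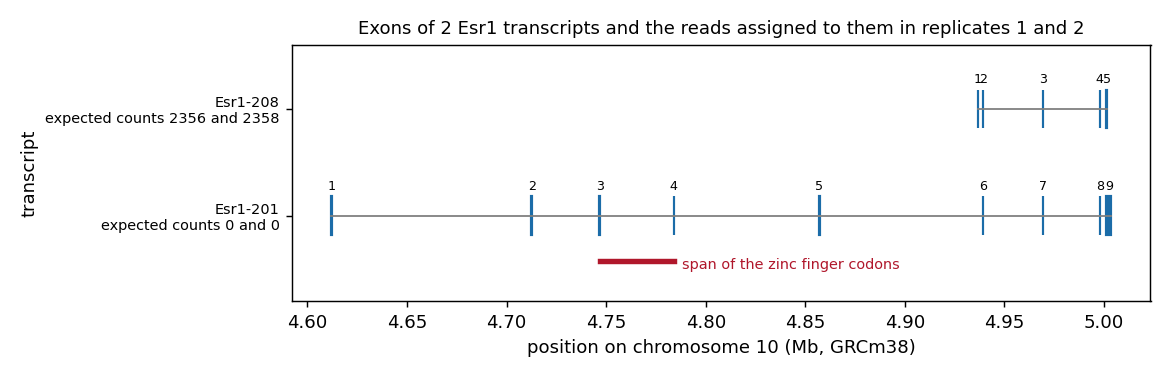
Exons of Esr1-208 and of the full-length Esr1-201 are drawn to position on chromosome 10 in Mb (GRCm38), with line width setting the narrowest exons and expected counts of replicates 1 and 2 at the left. Esr1-208 held 2356 and 2358 counts and covers only the part of the gene downstream of the zinc finger codons.

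The labels call the line male. Protein-coding genes of the Y chromosome held 3 counts in replicate 1 and 3 in replicate 2 over 183 listed genes. Eif2s3y, on chromosome Y from 1010543 to 1028847 with a unique share of 100%, had 2 and 0 counts, and Ddx3y, Uty and Usp9y had 0 in both libraries. Xist had 62.2 and 61.9 counts, or 0.340 ± 0.170 TPM, and the overlapping antisense gene Tsix 380 and 324 counts, which cannot be told apart without strand. Of the 10 genes in this list 1 was detected, and the median of 0 TPM lay at the percentile of 4.07. That percentile is set by ties at 0, and was 12.65 with posterior mean TPM and 8.14 among random lists not matched on length.

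Reference genes were detected in 16 of 16 cases, with Eef1a1 highest, Rpl13a at 4461 ± 388 TPM and Eef2 at 2903 ± 147 TPM. Their median of 923 TPM lay at the percentile of 100. Of 17 stress genes 12 were detected, including Hspa8 at 1523 ± 244 TPM, Hsp90ab1 at 1383 ± 29.03 TPM, Hsp90aa1 at 1130 ± 108 TPM and Ddit3 at 137 ± 6.38 TPM. The stress list had a median of 17.9 TPM, at the percentile of 99.3. Among genes at 1 TPM or more its percentile was 26.1, with undetected members kept in the list. Hspa8 and Hsp90aa1 had unique shares of 41.1% and 38.4%. Over all lists, 16 of 26 medians lay above the central 95% of random lists, and 297 of 440 different members were detected. With random lists drawn from genes at 1 TPM or more, 11 medians lay above it. That setting lowers lists with undetected members by construction, so the smaller number does not compare like with like.

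Some ratios depended on the division by effective length. From expected counts the log2 ratio was 6.11 for Bcl2l1 over Bcl2, 1.81 for Bcl2l1 over Mcl1, 3.42 for Ccnd3 over Ccnd2, 8.09 for Gata1 over Gata2 and -0.13 for Cdkn1b over Cdkn1a. None of the 15 ratios changed sign.

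Several erythroid genes were divided among transcripts. Of 40 genes fixed for this question, 27 had a leading transcript with 90% or less of the gene's TPM in both libraries. Gata1-201 held 99.5% ± 0.219 of Gata1, and Klf1, Fth1 and Epor were each assigned to 1 transcript. A gene with only 1 listed transcript has a share of 100% by construction. A transcript of 569 bases without annotated coding sequence held 48.3% ± 2.69 of the TPM of Alas2. This share depends on its short length, since its 3901 and 3367 expected counts were below those of the coding transcripts Alas2-201, with 6237 and 8641, and Alas2-202, with 7002 and 4950. Pkm-201 held 79.5% ± 0.332 of Pkm, Hk1-201 53.2% ± 1.11 of Hk1, Gfi1b-201 59.5% ± 0.146 of Gfi1b and Pklr-202 65.6% ± 0.154 of Pklr. The leading transcript differed between the libraries for 5 genes, among them Ftl1, Bnip3l, Epb41 and Bcl2l1. Ftl1-201 held 30.4% of Ftl1 in replicate 1 and 77.8% in replicate 2. With 36-base reads, overlapping transcripts of a gene share most of their reads, so these divisions are estimates.

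Rpl23a-ps3 and Rpsa-ps2, processed pseudogenes of ribosomal protein genes with unique shares of 8.08% and 18.5%, differed most in each direction between the replicates. Among 9360 genes with at least 50 counts on average, 101 differed over 2-fold, 70 of them higher in replicate 1, and 49 were processed pseudogenes. Poisson noise alone gave between 0 and 1 such genes in 100 simulated pairs. The count was 403 with a minimum of 10 counts on average and 45 with a minimum of 200. It was 29 among nuclear protein-coding genes and 9 of 6819 genes with unique shares of at least 90%, the latter a limit set after seeing the data. Rpl23a-ps3 had 4132 counts in replicate 1 and 0 in replicate 2, with deposited posterior SDs of 391 and 40.9 counts, followed by Gm10282, Srp54a, Gm12013 and Gm10698, which also had 0 counts in replicate 2. Rpsa-ps2 had 51 and 4310 counts and was 93.0-fold higher in replicate 2 (exact 95% interval 70.6 to 125), with posterior SDs of 22.3 and 249 counts, ahead of Gm8741, Mrpl23, Rpl17-ps5 and Gm28911. Mrpl23 was 12.0-fold higher in replicate 2 with an interval of 7.80 to 19.2, and posterior SDs of 101 and 144 counts. These SDs include errors in dividing shared reads, which the intervals leave out.

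Replication-dependent histone genes also differed. Of 12 with at least 50 counts on average, 11 were higher in replicate 1, and their median log2 ratio was 0.80 ± 0.28 (SD over resampled genes), beside 0.01 for nuclear protein-coding genes. Hist1h4d stood at 58.5 TPM in replicate 1 and 29.3 in replicate 2, Hist1h2ab at 30.4 and 11.8, Hist1h2ae at 25.2 and 21.6, and Hist1h2bc at 24.3 and 28.1. Their list had 18 of 25 genes detected and a median of 4.61 TPM, at the percentile of 99.9, but of 94.3 among random lists not matched on length. Among genes at 1 TPM or more its percentile was 0, with undetected members kept in the list.

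Across 11307 genes, log2(TPM + 1) of the replicates correlated with Pearson r = 0.978 ± 0.00127 and Spearman rho = 0.981 ± 0.00101 (SD over resampled genes). With the numbered rows included there were 12934 rows, r was 0.958 and rho 0.956. These are correlations across genes, which are not independent replicates. The biological coefficient of variation was 12.5% over 11078 genes, and 9.19% over the 7707 of them with unique shares of at least 90%.

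**Figure D3:**
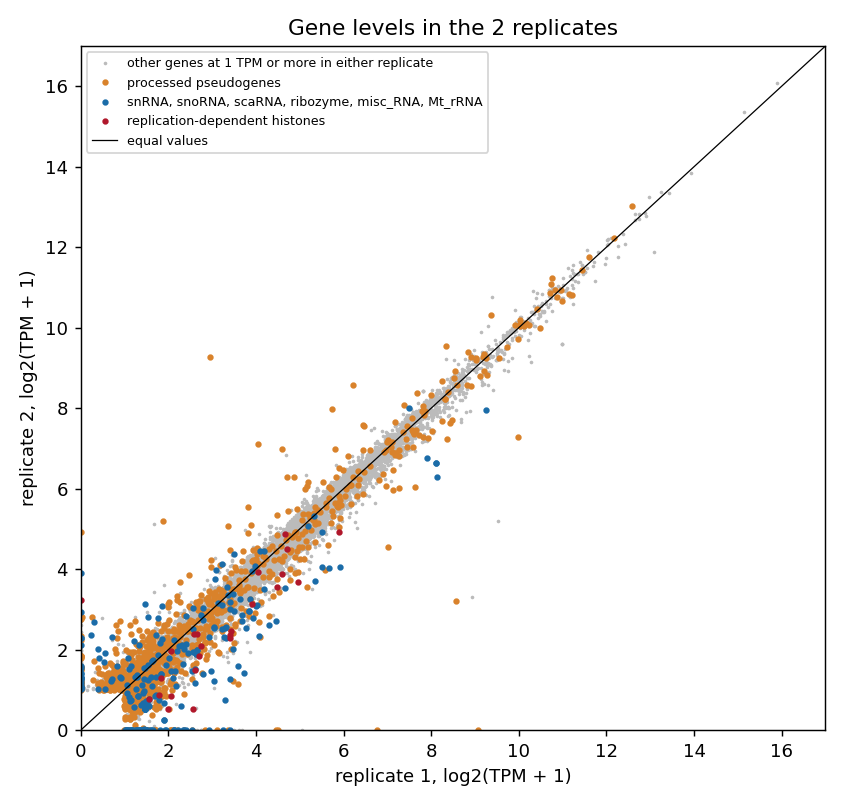
Each point is 1 gene at 1 TPM or more in either library, with log2(TPM + 1) of replicate 1 on the horizontal and of replicate 2 on the vertical axis, and the line marks equal values. Processed pseudogenes (orange) make up 49 of the 101 genes over 2-fold apart, and histones (red) lie mostly below the line.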

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

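The tests of the 3 patterns in this part were chosen, or their reading was set, after the results were seen, except the test of GC content.

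Rows of the gene tables that carry only a number, and so name no gene, held reads that no gene list, ratio, dispersion or fold count used, although they are part of the total depth. They had 2427 expected counts in replicate 1 and 2041 in replicate 2, summed over all 26248 rows. Of these rows 1084 reached 1 TPM in replicate 1, 966 in replicate 2 and 423 in both. On average, rows at 1 TPM thus held few counts each, near the floor of 3 counts set for a gene.

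No biological explanation was tested for any of the 3 patterns below through a group of samples, since the design has 1 group.

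Histone genes were higher in replicate 1, with a median log2 ratio of 0.80. The polyadenylated S-phase mRNAs Mcm2 to Mcm7, Pcna, Rrm2, Ccne1 and E2f1 had a median of -0.0384 with an SD of 0.13, which argues against more cells in S phase. After removal of the trend with GC content over nuclear protein-coding genes, the histone median was 0.86 ± 0.26, which argues against that trend as the cause. Other RNAs of classes without a long poly(A) tail, such as Rn7sk, Rmrp and mt-Rnr2, had a median of 1.30, and 10 of 11 were higher in replicate 1, although Rn7s1 and Rn7s2 among them hold identical values. Less complete poly(A) selection in replicate 1 may therefore underlie the difference and stays open.

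Genes over 2-fold apart were mostly ones whose sequence recurs elsewhere. Counting noise was simulated with at most 1 such gene, against 101 observed, which decides nothing, since separate samples differ by more than technical noise in any case. Of 98 differing genes with a measured unique share, 83.7% had less of their sequence unique than shared, beside 9.04% of all genes with at least 50 counts on average. A different division of the same reads among near-identical copies in each library is a candidate explanation that stays open. Of the 9 differing genes with unique shares of at least 90%, which include Hist1h1b, mt-Rnr1 and mt-Rnr2, Mrpl23 still had posterior SDs of 101 and 144 counts, so a unique share does not rule out shared reads.

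Reads of Esr1 lay on its last exons. At most 2.85% of them, in either library, were assigned to transcripts with the exons of the DNA-binding domain, which argues against expression of the full-length receptor. If every Gata1 read came from a fusion whose receptor part were identical to mouse Esr1, both parts would have similar read densities. Esr1-208 had 0.0545 of the reads per base of Gata1-201 at the most, which argues against that form of the explanation. A fusion whose receptor part differs in sequence from mouse Esr1, as a part from another species could, stays open, since the construct's sequence was not analysed here.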

How the results depend on the processing

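The alternatives with numbered rows included, with unique shares of at least 90%, and with nuclear protein-coding genes alone in the correlation were chosen after seeing the data. Apart from list percentiles, 83 of 123 alternative values stayed within the replicate spread, the resampling SD or 1.5 times the count, 40 moved and 0 changed sign. A mean over 2 libraries moves by less than 1 SD by construction when either is left out, so for shares and ratios those values say nothing about stability and swell the number that stayed. Counts of genes detected, of lists above the central 95% of random lists, of detected list members and of genes with shared transcripts all stayed within 1.5 times, also with either replicate left out. For the lists, the number still fell from 16 to 11 with random lists drawn from genes at 1 TPM or more. The lists kept their undetected members there, which lowers their percentiles by construction. Depth limits statements on genes near 0, such as lineage markers with 1 to 3 counts.

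Pearson r was 0.942 with a pseudocount of 0.1, 0.993 over all genes without a filter, where most genes are at 0 in both libraries, 0.989 with posterior mean TPM, 0.958 with numbered rows included and 0.991 for nuclear protein-coding genes alone. Spearman rho was 0.906, 0.979, 0.956 and 0.991 in the latter 4 settings. The coefficient of variation was 13.7% without a filter on low counts, 11.3% with at least 100 counts and 9.19% for unique shares of at least 90%. Genes over 2-fold apart numbered 403 with at least 10 counts on average, 45 with at least 200, 29 for nuclear protein-coding genes and 9 for unique shares of at least 90%, all sets of another size by construction. The share of expected counts, which gives no weight to length, was 4.79% for adult globins, 2.80% for mitochondrially encoded genes, 5.96% for ribosomal protein genes, 9.88% for the 10 and 27.7% for the 100 most abundant genes. With protein-coding genes alone in the denominator these were 13.3%, 5.82%, 13.9%, 20.9% and 44.4%. The log2 ratio of adult alpha over beta globins was -0.59 from expected counts. The cause of the other shifts was not tested. Of 56 values for the other ratios 43 stayed within 1 SD, among them all with a library left out, and 13 moved. Among 156 list percentiles 6 crossed the upper bound of the central 95%, of which 5 came from random lists of genes at 1 TPM or more, and larger shifts that stayed below that bound are not counted.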

Other observations

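Ribosomal protein genes, which formed no list of their own although the reference genes include Rplp0 and Rpl13a, were abundant as a group. Of 76 such genes 75 were detected in both libraries, Rps27 had 0 counts in both, and the median was 1189 TPM. The genes below were chosen after their values were seen. Some members were listed below a processed copy. Rps13 stood at 57.0 ± 32.3 TPM and its pseudogene Rps13-ps1 at 1102 ± 91.5 TPM (SD, n = 2), and Rpsa stood at 2719 ± 175 TPM beside 7228 ± 1562 TPM for Rpsa-ps10. Named ribosomal protein pseudogenes held 2.84% of TPM in replicate 1 and 3.09% in replicate 2, and 85 of 252 were detected. Unique shares were 8.95% for Rps13-ps1 and 12.5% for Rpsa-ps10, so levels of single members are uncertain.

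Other abundant genes outside the lists, also chosen after their values were seen, were Blvrb, which encodes biliverdin reductase B, at 1924 ± 137 TPM, the metallothionein gene Mt1 at 1610 ± 96.8 TPM, the transketolase gene Tkt at 1650 ± 249 TPM and Tuba4a at 2878 ± 156 TPM. Gm42418, annotated as a long intergenic RNA with a unique share of 4.23%, had 250683 counts in replicate 1 and 98278 in replicate 2. Of mitochondrially encoded mRNAs, mt-Co3 stood at 732 TPM in replicate 1 and 35.8 TPM in replicate 2, with a unique share of 0.134%, while mt-Nd2 stood at 7459 ± 99.7 TPM with 88.9%. Between the libraries, the median log2 ratio of nuclear protein-coding genes was 0.32 in the 1 of 20 bins with the lowest GC content and -0.07 in that with the highest.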
